A study of Mus musculus with 33 samples.

How the data were processed

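The series holds 33 samples of mouse CD4+ Tconv, each read on 1 Affymetrix array from total RNA. The values are the deposited intensity per probe, and per the submitters' processing notes they were made with RMA in Affymetrix Power Tools, for which no version is given. RMA gives log2 values, but the deposited intensity table held values from 5.03 to 25902 and was therefore on a linear scale, so log2 was taken. What the submitters did to return the values to a linear scale is not recorded. No genome build is given, and no coordinates are reported.

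The table held 24922 probes. The platform annotation paired 21425 of them with 1 gene symbol and 1399 with several, and 2098 were unnamed; only probes with 1 symbol were used, and 0 symbols needed an update through the gene identifiers. For a gene with several probes the one with the highest mean was taken, which left 19752 genes. A gene was tested if it was at or above the median of all probes in at least 2 arrays, which left 10928 genes. The precision of every value is limited by the number of arrays.

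Groups and replicate numbers came from the labels: 16 groups of 2 arrays and 1 array of FOXP3+Pbx1. All 33 arrays entered 1 limma fit (version 3.58.1, R 4.3.3) with a mean per group and 16 residual degrees of freedom, and eBayes moderated tests were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The 23 comparisons were FOXP3 against vector, FOXP3 in the 7 cofactor backgrounds (the mean over cofactors of cofactor with FOXP3 minus cofactor alone), each cofactor against vector, each cofactor with FOXP3 against FOXP3, and the 7 interactions. Of 29 gene lists fixed from textbook knowledge, 25 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 575 tests; 184 passed. With an estimated correlation 0 passed, with a smallest adjusted p of 0.0931, and fry, which tests whether a list's genes move one way, passed 2. The 4 lists with fewer genes, for Th17 cells, mast cells, gamma-delta T cells and sex-linked genes, had 4, 2, 2 and 1 tested genes and no test. Transduced genes were left out of every list. List shifts across the 8 backgrounds were tested with a 2-sided exact sign-flip permutation test.

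Genes were named by rule: those that passed with each array of one group beyond each array of the other or, for the 7 cofactor backgrounds, with the same sign in all 7, up to 12 rises and 12 falls for the FOXP3 comparisons and 6 or 3 each way for the others; predicted genes were skipped. Where none passed, the 2 genes with the smallest p were taken, and of these the text gives 1 or 2. For FOXP3+Pbx1 the 5 largest differences each way were named. Of each list described, up to 4 members with the smallest p were named. The comparisons, lists, naming rule and the first 7 kinds of alternative below were fixed before the data were examined. Cd74, Trgv1, Jun, Nedd4, Slc26a11, Pim2, Cpe, Ifi208, Tle4 and Rtp4 came from a like rule with the set as a block. There the signs were taken after the block or, between 2 groups, inside each set. Without the block Jun had the same sign in 6 and Pim2 in 3 of the 7 cofactor backgrounds. The levels of Irf4 and Lef1 by set were chosen after their values were seen.

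The alternatives were no filter, quantile normalization, the mean over a gene's probes, an offset of 32 before taking log2, only the arrays of the comparison, the replicate number as a block, and leaving out each replicate, where a lone array is taken to vary like the other groups. The 4 sets of arrays were found from correlations between arrays. The set as a block with the single set D array left out, leaving out set C, and differences inside set A or set B were chosen after seeing the data. Tested on simulated data with 200 changed genes of 10928, FOXP3 against vector recovered 9.88% of changes of 0.5, 50.9% of changes of 1 and 85.9% of changes of 2 on the log2 scale with 2 false calls, and the 7 cofactor backgrounds 76.5%, 96.4% and 100% with 13 false calls. The simulated arrays varied independently and held no sets, so these rates check the code and do not describe the real arrays.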

Results

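Gene expression was measured with 33 Affymetrix arrays in lymph node CD4+ conventional T cells (Tconv) of female B6 mice aged 8 weeks. The cells were activated with beads against CD3 and CD28, transduced with retroviral vectors, cultured for 3 days and sorted. An empty vector, FOXP3, and each of 7 possible partner factors alone or with FOXP3 made 16 groups of 2 arrays. The partners, called cofactors here, were XBP1, SATB1, LEF1, IRF4, Helios, GATA1 and EOS. A single array held FOXP3 with Pbx1. The design asks how FOXP3, the defining transcription factor of regulatory T cells (Treg), and its candidate cofactors shape the genes typical of Treg. The number of arrays limits the precision of each value. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these arrays.

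The arrays fell into 4 sets that the labels do not name, and these sets moved with FOXP3. Set A held 11 arrays (3 with FOXP3), set B 16 (8 with and 8 without FOXP3), set C 5 (all FOXP3 with a cofactor) and set D the single Pbx1 array. Set C stood apart in T cell genes. Irf4, a factor induced by antigen receptor signalling, had intensities of 887 to 1170 there and at most 466 elsewhere. Lef1, a factor of naive T cells, had 1444 to 1662 there and at least 2603 elsewhere. Over the arrays with FOXP3, the list of 16 naive T cell genes averaged 8.65 on the log2 scale in set C and 9.45 in set B. Arrays of different groups in the same set correlated at a median r of 0.983 across genes, and the 2 arrays of a group, which lay in different sets, at 0.950 (genes are not independent replicates). Values with the set as a block (chosen after seeing the data) and inside set B therefore stand beside the results they moved. Leaving out 1 of the 2 arrays of a group also left that group in a single set. A mean or call lost there can reflect the sets as well as that array. The fit of all arrays held no term for the sets, so differences between sets added to its spread.

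**Figure D1:**
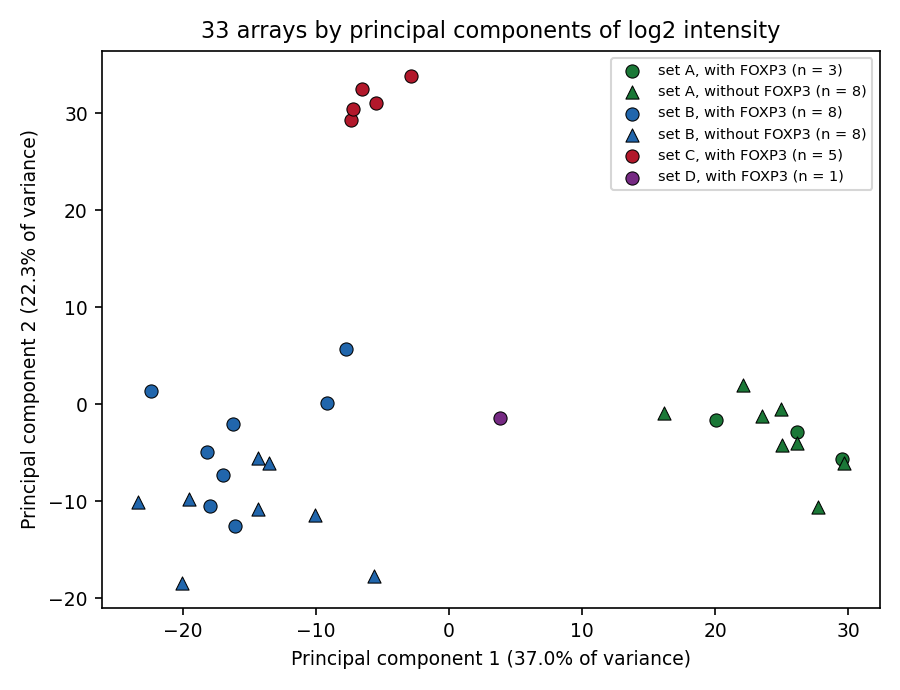
Each point is 1 array, placed on the first principal components of log2 intensity over the genes tested (37.0% of the variance on the x axis and 22.3% on the y axis), with colours for the 4 sets and circles or triangles for arrays with or without FOXP3. The 5 set C arrays, all with FOXP3, lie apart along the y axis, and sets A and B lie apart along the x axis.

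The transduced genes were read first. Foxp3 intensity was 137 to 203 in the 17 arrays with FOXP3 and 104 to 141 in the 16 without. The difference was 0.51 on the log2 scale over the 7 cofactor backgrounds (SE 0.0649, limma adjusted p = 0.000541) and 0.28 against vector (SE 0.172, adjusted p = 1). Ikzf4, which encodes EOS, had 180 to 417 in the 4 EOS arrays and 98.9 to 273 in the others, and Ikzf2, which encodes Helios, 210 to 663 in the 4 Helios arrays and 148 to 395 in the others. Neither passed against vector (log2 differences 0.61 and 1.02, adjusted p = 1 for both). The intensities of Gata1, Irf4, Lef1, Satb1 and Xbp1 in their own arrays overlapped those of the other arrays. Against vector their log2 differences were 0.08, −0.35, −0.19, −0.21 and 0.23, with adjusted p = 1 for each. Which part of each transcript the probes cover is not given, so a probe outside the transduced sequence would check nothing. No probe carried the symbol Pbx1.

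FOXP3 in the 7 cofactor backgrounds raised genes of regulatory and cytotoxic T cells. Lrrc32, which encodes the Treg surface protein GARP, rose by 1.33 on the log2 scale (SE 0.287, adjusted p = 0.0298) and Tnfrsf9, the receptor 4-1BB, by 1.04 (SE 0.218, adjusted p = 0.0267), with 14 arrays on each side. Gzmb, which encodes granzyme B, rose by 1.26 (SE 0.277, adjusted p = 0.0318) and Lta, which encodes lymphotoxin alpha, by 1.02 (SE 0.251, adjusted p = 0.0483). Socs2, a STAT5-induced regulator of cytokine signalling, rose by 1.19 (SE 0.254, adjusted p = 0.0285). Il2ra, the high-affinity IL-2 receptor chain CD25, rose by 0.83 (adjusted p = 0.00831) and Il2rb, its signalling partner, by 0.63 (adjusted p = 0.00126). Further rises among the largest were Ccn3 (1.46), Nrn1 (1.27), Enah (1.17), Neb (1.01), Cyp11a1 (1.00), Tgm2 (0.98) and the surface protein gene Thy1 (0.93). Whether the FOXP3 construct itself carries a Thy1 sequence is not known. Bcl6, the transcription factor of follicular helper T cells, fell by 1.02 (SE 0.197, adjusted p = 0.0153) and St3gal6, a sialyltransferase gene, by 0.79 (SE 0.137, adjusted p = 0.00831). Other falls were Lypd6b (−1.24), Gramd3 (−1.06), Pik3ip1, a negative regulator of PI3K (−0.80), Rnf32 (−0.79), Rnf144a (−0.75), Scml4 (−0.72), Arhgap29 (−0.66), Als2cl (−0.62), Fam78a (−0.61) and Tmie (−0.53).

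In all, 136 genes rose and 36 fell of 10928 tested in the 7 cofactor backgrounds (99 and 57 after quantile normalization, 85 and 16 with no filter, and 1040 and 470 with the replicate number as a block). Of these 172 genes, 167 (97.1%) had the same sign in FOXP3 against vector, which shares no array with this comparison, against 63.2% of all genes. When the set was a block, 57 genes passed (52 higher, 5 lower). Both fits use the same arrays but for the Pbx1 array, so an overlap is built in and is no replication. Of the 57 genes, 38 were among the 172, and all 172 had the same sign with the set block. Gzmb (1.12), Tgm2 (0.96), Lrrc32 (0.93), Ccn3 (0.81), Cyp11a1 (0.79), Neb (0.75), Thy1 (0.73), Il2ra (0.58), Lta (0.55), Enah (0.50), St3gal6 (−0.53) and Tmie (−0.39) passed there too. The other 13 of the 24 genes named by rule lost their call, among them Bcl6 (−0.59, adjusted p = 0.139), Tnfrsf9 (0.57, adjusted p = 0.226), Socs2 (0.50, adjusted p = 0.0675) and Nrn1 (0.67, adjusted p = 0.109). Trgv1 (0.80 with the block) and Nedd4 (0.55) also passed both ways, while Jun (0.69), Cd74 (0.62), Slc26a11 (−0.28) and Pim2 (−0.28) passed only with the block. Inside set B, with 8 pairs of arrays, the mean difference was 1.26 for Gzmb (SD 0.176, higher in 8 of 8), 0.70 for Lrrc32 (SD 0.345, 8 of 8), 0.56 for Il2ra (SD 0.187, 8 of 8) and −0.75 for Bcl6 (SD 0.535, lower in 8 of 8). In the 3 backgrounds of set A the means were 1.77 for Lrrc32 (higher in 3 of 3), 0.81 for Il2ra (3 of 3) and −1.03 for Bcl6 (lower in 3 of 3), but 0.25 for Gzmb (SD 0.666, higher in 1 of 3) and −0.01 for Tnfrsf9 (SD 0.49, 1 of 3). The count was 8 without the 5 set C arrays. Leaving out 1 of the 28 arrays gave fewer calls for 23 of them (40 to 138): 40 to 61 without replicate 2 of EOS, GATA1, Helios, IRF4, SATB1 or XBP1 or LEF1 replicate 3, 40 to 44 without replicate 2 of GATA1, SATB1, EOS, IRF4 or LEF1 with FOXP3, 44 without Helios+FOXP3 replicate 3, 48 without XBP1+FOXP3 replicate 3, 58 without SATB1 replicate 3, 89 without IRF4 replicate 3, 103 without XBP1+FOXP3 replicate 2, 126 without Helios replicate 3 or LEF1 replicate 4, and 129, 132, 134 and 138 without EOS replicate 3, XBP1 replicate 3, Helios+FOXP3 replicate 2 and GATA1 replicate 3. It gave more calls for 5: 217 without GATA1+FOXP3 replicate 3, and 363 to 498 without replicate 3 of IRF4, SATB1, EOS or LEF1 with FOXP3. Of the 24 genes named by rule, 24 kept their sign in every such run and 7 their call.

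**Figure D2:**
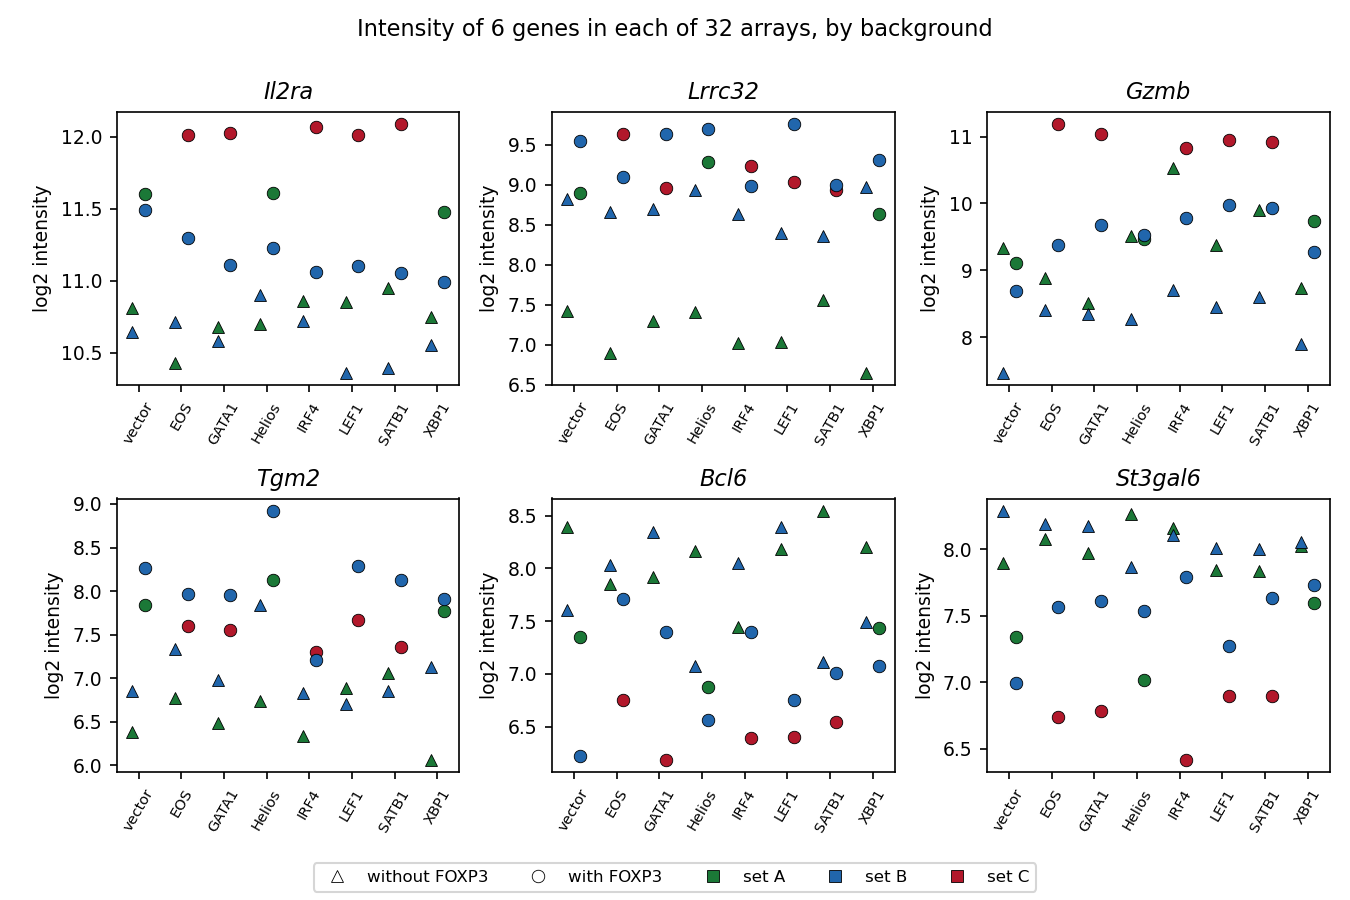
Log2 intensity (y axis) of 6 genes in each of 32 arrays by background (x axis), with circles for arrays with FOXP3, triangles for arrays without, and colours for the sets. Il2ra, Bcl6, St3gal6 and Tgm2 part the arrays with FOXP3 from those without in each of 8 backgrounds, and inside set B FOXP3 arrays are higher for Il2ra, Lrrc32 and Gzmb and lower for Bcl6 in 8 of 8 backgrounds.

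As a group, genes that are higher in Treg than in Tconv shifted up with FOXP3. Of the 45 genes tested on the list of Treg-up genes, 44 had a positive difference in the 7 cofactor backgrounds, with a mean of 0.49 (SD 0.361). Of these, 16 rose over all genes tested, and 35 rose and 1 fell adjusted over the list alone. The largest tests were those of Il2rb, Il2ra, Gpr83 (0.41, adjusted p = 0.021) and Tnfrsf9. The set test camera gave adjusted p = 9.21e-20 with a preset correlation, and adjusted p = 0.336 with an estimated correlation. The mean with the set block was 0.25 (camera adjusted p = 1.43e-15; adjusted p = 0.189 with an estimated correlation). The list shift was positive in 8 of 8 backgrounds including vector, with a mean of 0.47 (SD 0.162, n = 8 backgrounds). The 2-sided exact sign-flip p was 0.00781, the smallest this design allows, and 0.0279 after Benjamini-Hochberg adjustment over the 25 lists. Inside set B the shift was positive in 8 of 8, with a mean of 0.24 (SD 0.12, n = 8, exact p = 0.00781, 0.0325 after adjustment).

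**Figure D3:**
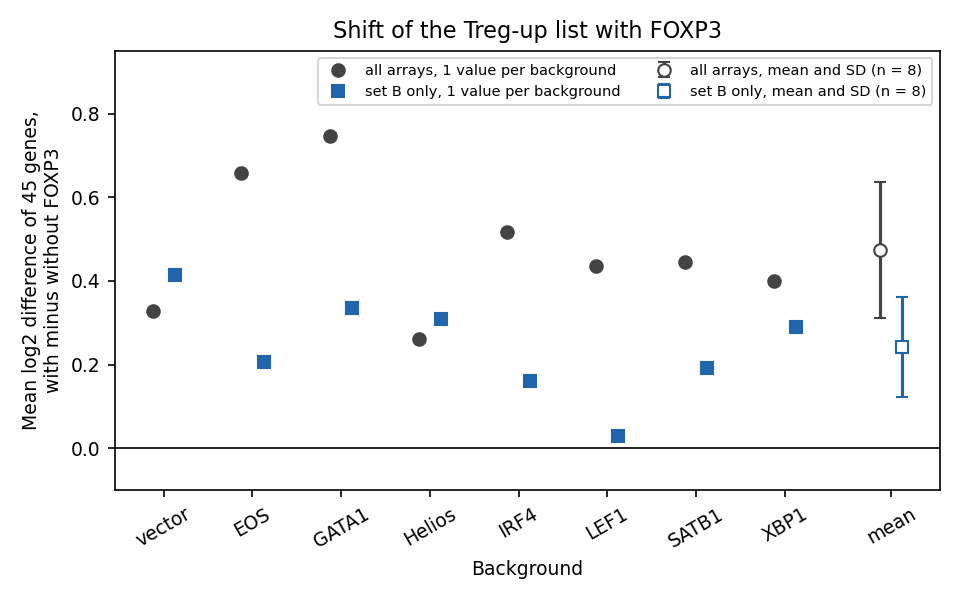
Mean log2 difference of the 45 Treg-up genes between arrays with and without FOXP3 (y axis) in the vector and 7 cofactor backgrounds (x axis), over all arrays (circles) and inside set B (squares), with open symbols for the mean and bars for the SD over 8 backgrounds. All 16 values lie above 0, and the means are 0.47 over all arrays and 0.24 inside set B.

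Genes of IL-2 signalling, glycolysis and cytotoxicity also shifted up in the 7 cofactor backgrounds. The 19 genes of the STAT5 and IL-2 response averaged 0.43 (SD 0.359, camera adjusted p = 1.53e-10; adjusted p = 0.336 with an estimated correlation), with 14 members higher adjusted over the list alone and 6 over all genes, among them Il2ra, Il2rb, Socs2 and the survival gene Bcl2l1 (0.33, adjusted p = 0.00917). The 22 glycolysis and hypoxia genes averaged 0.38 (SD 0.279, camera adjusted p = 9.95e-12; adjusted p = 0.466 with an estimated correlation), with 18 members higher and 1 lower adjusted over the list alone and 8 higher over all genes, including the glycolytic enzyme gene Pgam1 (0.60), the mitophagy receptor gene Bnip3 (0.91), Ero1a (0.67) and P4ha1 (0.33). The 10 cytotoxic genes averaged 0.44 (SD 0.449, camera adjusted p = 0.00177; adjusted p = 0.402 with an estimated correlation), where Nkg7 (0.84, adjusted p = 0.0118) and Gzmb rose and 5 members passed adjusted over the list alone. The 15 effector genes downstream of IRF4 and BLIMP1 averaged 0.52 (SD 0.328, camera adjusted p = 1.66e-07; adjusted p = 0.557 with an estimated correlation), with 2 higher over all genes and 11 adjusted over the list alone. The means of these 4 lists with the set block were 0.23, 0.21, 0.32 and 0.21, and each still passed camera (adjusted p = 1.05e-07, 1.2e-07, 0.000268 and 0.00226; with an estimated correlation adjusted p = 0.189, 0.453, 0.264 and 0.44). With the block 7 of 7 B cell markers, which belong to another cell type, were also positive, with a mean of 0.32 as large as that of the cytotoxic list (camera adjusted p = 7.47e-05; adjusted p = 0.353 with an estimated correlation).

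Naive T cell genes and Treg-down genes were lower with FOXP3, in amounts that followed the sets. In the 7 cofactor backgrounds the naive list averaged −0.47 (camera adjusted p = 6.53e-07; adjusted p = 0.572 with an estimated correlation), with Als2cl lower over all genes and 5 members adjusted over the list alone. The 21 Treg-down genes averaged −0.33 (camera adjusted p = 0.000107; adjusted p = 0.557 with an estimated correlation), with Arhgap29 lower over all genes, and 9 lower and 1 higher adjusted over the list alone. Cd40lg, which encodes the CD40 ligand of helper T cells, stood at −0.64 and did not pass (adjusted p = 0.0601). The Treg-down shift over all 8 backgrounds was −0.33 (SD 0.169, lower in 7 of 8, exact p = 0.0156), and inside set B −0.06 (SD 0.21, lower in 5 of 8, exact p = 0.547). In the 3 backgrounds of set A it was −0.19 (SD 0.123, lower in 3 of 3), and that of the naive list −0.17 (SD 0.0484, 3 of 3). The cell cycle list (0.28, camera adjusted p = 9.31e-06; adjusted p = 0.794 with an estimated correlation), the amino acid stress genes downstream of ATF4 and CHOP (0.44, camera adjusted p = 0.000139; adjusted p = 0.794 with an estimated correlation) and the unfolded protein response genes of XBP1 (0.13, camera adjusted p = 0.000353; adjusted p = 0.731 with an estimated correlation) passed in the same comparison. A block for the set gave means of −0.02 for the naive list, −0.04 for Treg-down, 0.01 for cell cycle and 0.02 for XBP1, and these 4 calls were lost (camera adjusted p = 0.702, 0.34, 0.894 and 0.624). The ATF4 and CHOP list turned to −0.11 and was called lower (adjusted p = 0.00973; adjusted p = 0.748 with an estimated correlation).

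FOXP3 alone against vector, with 2 arrays on each side, was read for the gene groups called in the 7 cofactor backgrounds. Treg, glycolysis, IL-2 and naive T cell genes passed, and cytotoxic (0.02), cell cycle (0.01), XBP1 (0.04), ATF4 and CHOP (0.16) and IRF4 and BLIMP1 genes (0.18) did not (camera adjusted p = 0.893, 0.641, 0.277, 0.202 and 0.179). With the set block the last 2 passed (camera adjusted p = 0.0312 and 0.0418; adjusted p = 0.804 and 0.638 with an estimated correlation). Their differences from vector were 0.76 and 0.38 inside set B. In set A the ATF4 and CHOP list was lower with FOXP3 in 3 of 3 backgrounds, vector among them (mean −0.20). The Treg-up list averaged 0.33 (SD 0.348, 37 of 45 genes positive, camera adjusted p = 9.73e-08; adjusted p = 0.557 with an estimated correlation), with Il2ra at 0.82, Il2rb at 0.56 and Gpr83 at 0.55. The glycolysis and hypoxia list averaged 0.36 (21 of 22 positive, camera adjusted p = 1.38e-08; adjusted p = 0.557 with an estimated correlation) and the STAT5 and IL-2 list 0.27 (15 of 19 positive, camera adjusted p = 0.00131; adjusted p = 0.668 with an estimated correlation). The naive list averaged −0.44 (15 of 16 genes negative, camera adjusted p = 0.00108; adjusted p = 0.731 with an estimated correlation), with Ccr7, the lymph node homing receptor, at −0.55, and the Treg-down list −0.32 (19 of 21 negative, camera adjusted p = 0.00207; adjusted p = 0.668 with an estimated correlation), with Il2 at −0.76. Of the 5 genes tested from a fibroblast list (mean 0.33, camera adjusted p = 0.000497; adjusted p = 0.477 with an estimated correlation), Thy1, which mouse T cells also express, stood at 1.03 and the collagen genes Col5a1, Col3a1 and Col1a1 at 0.26, 0.19 and 0.18. No single gene passed with limma (0 of 10928, with 138 at an unadjusted p under 0.05 where 546 are expected by chance). Cfap77 (0.80) and Sdc4 (0.68) had the smallest limma p-values and did not pass (adjusted p = 1). With the set block 6 genes passed at limma adjusted p = 0.0431, with 798 at an unadjusted p under 0.05. Tgm2 (1.44), Enah (1.35), Cpe (1.00) and Cfap77 (0.80) were higher and Ifi208 (−1.13) and Tle4 (−0.68) lower. The SD of the 2 FOXP3 arrays, which lay in different sets, was 1.7 for Ifi208, 1.24 for Enah, 0.855 for Cpe and 0.559 for Tle4. It was 0.296 for Tgm2 and 0.191 for Cfap77. Without FOXP3 replicate 3 the means were −0.12 for Treg-down, −0.09 for naive, 0.13 for STAT5 and IL-2 and −0.04 for glycolysis and hypoxia, and these 4 no longer passed. Treg-up was then 0.23 and passed. Without vector replicate 2 the Treg-down and naive means were −0.32 and −0.34 and did not pass.

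Gene groups of proliferation, activation and interferon signalling differed between single cofactors and vector, while no single gene passed. With IRF4, all 37 cell cycle genes had a positive difference from vector, with a mean of 0.52 (SD 0.142, camera adjusted p = 2.8e-15; adjusted p = 0.644 with an estimated correlation), and at least 0.37 without any 1 array; Cenpe stood at 0.78 and Top2a at 0.61. The same list averaged 0.50 with LEF1, 0.42 with Helios, 0.40 with SATB1 and 0.26 with EOS (camera adjusted p = 1.08e-14, 8.81e-09, 2.52e-09 and 2.96e-05; adjusted p = 0.658, 0.74, 0.731 and 0.794 with an estimated correlation), and 0.05, 0.03, 0.05 and −0.21 without LEF1 replicate 4, Helios replicate 3, SATB1 replicate 3 and EOS replicate 3, where the calls were lost. Each group here had 1 array in set A and 1 in set B. Leaving out 1 array therefore compared 1 set with both. Inside set A the list differed from vector by 0.205 with LEF1, 0.186 with Helios, 0.203 with SATB1 and −0.0568 with EOS. Inside set B it differed by 0.786, 0.646, 0.595 and 0.57. With the replicate number as a block the LEF1 mean turned to −0.20. Only LEF1 had a replicate 4, so this block left its replicate 3, a set A array, alone among replicate 3 arrays of set B. The immediate response genes of T cell activation and NF-kB were lower with EOS (mean −0.52, 21 of 24 negative, camera adjusted p = 1.83e-07; adjusted p = 0.336 with an estimated correlation) and with IRF4 (−0.52, camera adjusted p = 3.92e-06; adjusted p = 0.336 with an estimated correlation), with Tnfaip3, a feedback inhibitor of NF-kB, at −1.05 and −1.18. Without vector replicate 2 the means were −0.25 and −0.26, and the calls were lost. Type I interferon genes were lower with IRF4 (mean −0.31, 20 of 24 negative, camera adjusted p = 0.00309; adjusted p = 0.668 with an estimated correlation), with Rtp4 at −1.76, Irf7 at −0.66 and Usp18 at −0.59, and the mean was −0.06 without IRF4 replicate 3 and −0.11 without vector replicate 2, where the call was lost. Inside the sets the interferon list level was 7.67 with IRF4 and 7.93 with vector in set A, and 7.16 and 7.53 in set B. The IRF4 array had the lowest interferon list level of the 11 arrays of set A and of the 16 of set B. IRF4 with FOXP3 was lowest of the 5 arrays of set C, but 11 of 16 from the lowest in set B.

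Markers of other cell types also differed among the single cofactors. With LEF1 the 7 B cell markers averaged 0.69 (7 of 7 positive, camera adjusted p = 3.13e-05; adjusted p = 0.557 with an estimated correlation), with the class II gene H2-Ab1 at 0.80, Cd74 at 1.26 and H2-Aa at 1.44, and with SATB1 0.50 (camera adjusted p = 0.0045; adjusted p = 0.731 with an estimated correlation). Without vector replicate 3 these means were 0.30 and 0.11, and the calls were lost, as they were without LEF1 replicate 3 (0.53) and SATB1 replicate 2 (0.11). With SATB1 the 6 CD8 and NK markers averaged 0.64 and the cytotoxic list 0.45 (camera adjusted p = 0.00832 and 0.0133; adjusted p = 0.477 and 0.557 with an estimated correlation), and 0.23 and 0.22 without vector replicate 3, and 0.48 and 0.29 without SATB1 replicate 2, where both calls were lost. XBP1 and GATA1 had lower activation and NF-kB genes (−0.31 and −0.33, camera adjusted p = 0.0218 and 0.0313; adjusted p = 0.726 and 0.731 with an estimated correlation), with −0.04 and −0.06 without vector replicate 2, −0.34 and −0.33 without replicate 2 of the cofactor, and −0.29 and −0.33 without its replicate 3. Neither passed in any of these runs. The 45 unfolded protein response genes of XBP1, a factor of the secretory pathway, did not pass with XBP1 itself. By limma 0 genes passed for each of the 7 single cofactors, with 54 (EOS) to 145 (SATB1) at an unadjusted p under 0.05. The smallest p-values, none of which passed, were those of Tox4 with GATA1 (−0.62, adjusted p = 0.807), Kif3c with SATB1 (−0.57), Tor3a with IRF4 (−0.52), H2-Eb1 with LEF1 (1.07), Sik3 with XBP1 (−0.52), Pon3 with EOS (0.73) and Osgepl1 with Helios (0.44), with adjusted p = 1 for the last 6. With the set block Rtp4 (−1.76, adjusted p = 0.0443) and Ifi208 (−1.27, adjusted p = 0.0314) were lower with IRF4, and no gene passed for the other 6. The block lowered the median SE from 0.24 to 0.164. With it 331 (EOS) to 715 (IRF4) genes had an unadjusted limma p under 0.05, where 546 are expected by chance. Differences between sets thus widened the spread without the block, and the lack of calls there does not show that no gene changed. All 7 comparisons share the same vector arrays, so their list shifts are not independent.

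Adding a cofactor to FOXP3 was read against FOXP3 alone, and cytotoxic genes were higher in each of the 7 combinations. Replicate 2 of 5 combinations lay in set C, whose arrays averaged 0.73 above the FOXP3 arrays of set B for this list, and FOXP3 alone had no array there. The 10-gene cytotoxic list averaged 0.84 with SATB1 (SD 0.64, 10 of 10 positive, camera adjusted p = 3.18e-07; adjusted p = 0.142 with an estimated correlation), and at least 0.61 without any 1 array, with Nkg7 at 1.45 and Gzmb at 1.53. The 6 CD8 and NK markers, which belong to other cell types, were higher in the same comparison (0.75, 5 of 6 positive, camera adjusted p = 0.044; adjusted p = 0.611 with an estimated correlation), a call lost without FOXP3 replicate 3 (0.41) or SATB1+FOXP3 replicate 3 (0.79). SATB1+FOXP3 replicate 2 lay in set C, whose arrays averaged 0.79 above the FOXP3 arrays of set B for these markers. The mean of the cytotoxic list was 0.67 with LEF1, 0.65 with EOS, 0.65 with GATA1, 0.52 with IRF4, 0.37 with XBP1 and 0.25 with Helios (camera adjusted p = 0.000139, 0.00112, 0.000614, 0.00528, 0.00186 and 0.0124; adjusted p = 0.336, 0.365, 0.336, 0.477, 0.402 and 0.557 with an estimated correlation). Each of these 6 calls was lost without FOXP3 replicate 3, and 5 of them also without an array of the combination. The lowest means were 0.31 without LEF1+FOXP3 replicate 2, 0.16 without EOS+FOXP3 replicate 2, 0.21 without GATA1+FOXP3 replicate 2, and 0.28 (IRF4), 0.14 (XBP1) and 0.02 (Helios) without FOXP3 replicate 3. With the set block the means were 0.67 (SATB1), 0.50 (LEF1), 0.48 (EOS), 0.48 (GATA1), 0.35 (IRF4), 0.37 (XBP1) and 0.25 (Helios), and each passed (camera adjusted p from 1.76e-08 to 0.0198; adjusted p from 0.189 to 0.446 with an estimated correlation). All 7 share the same FOXP3 arrays, and with no effect at all 13.2% of simulated sets of 7 groups lay above a shared control. The simulation held no sets of arrays, while 5 combinations had an array in set C, so this share is no chance rate for these data. Th1 genes averaged 0.46 with EOS, 0.43 with IRF4, 0.42 with GATA1 and 0.36 with SATB1 (camera adjusted p = 0.00494, 0.000856, 0.00453 and 0.00312; adjusted p = 0.336 for each with an estimated correlation), and these 4 calls were lost without FOXP3 replicate 3 (0.46, 0.43, 0.42 and 0.36). They were lost for EOS, GATA1 and SATB1 also without replicate 2 of the combination (0.25, 0.29 and 0.20).

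With IRF4 and FOXP3, gene groups of helper T cells were higher than with FOXP3 alone. Th2 genes averaged 0.69 (11 of 11 positive), effector cytokines 0.71 (13 of 15), the effector genes of IRF4 and BLIMP1 0.68 (14 of 15) and Tfh genes 0.37 (10 of 11). These had camera adjusted p = 6.62e-06, 4.4e-05, 6.53e-07 and 0.00417, and adjusted p = 0.557, 0.477, 0.559 and 0.452 with an estimated correlation. The T helper gene Gata3 stood at 0.69, Ifng at 1.19 and Tigit at 0.96. IRF4+FOXP3 replicate 2 lay in set C, and without it the first 3 means were 0.16, 0.26 and 0.27 and their calls were lost. The Tfh call was lost without FOXP3 replicate 3 (0.28). Replicate 2 of EOS, GATA1, LEF1 and SATB1 with FOXP3 also lay in set C, so high levels there were not particular to IRF4. Th2 log2 levels were 7.859 to 8.271 in set C and at most 7.298 in the FOXP3 arrays of sets A and B. Effector cytokines had 7.242 to 7.657 against at most 6.795, and the IRF4 and BLIMP1 genes 8.635 to 8.714 against at most 7.917. Tfh levels in set C lay within the range of sets A and B. With the set block the 4 means were 0.28, 0.25, 0.25 and 0.24. Cholesterol synthesis genes averaged 0.35 (18 of 20 positive, camera adjusted p = 2.22e-05; adjusted p = 0.699 with an estimated correlation), with Idi1 at 1.01 and Cyp51 at 0.73, and 0.11 without either IRF4+FOXP3 replicate 3 or FOXP3 replicate 2, where the call was lost. With XBP1 and FOXP3 the Treg-down list averaged 0.24 (19 of 21 positive, camera adjusted p = 0.0313; adjusted p = 0.783 with an estimated correlation), and 0.03 without FOXP3 replicate 3 and 0.18 without XBP1+FOXP3 replicate 2, where the call was lost. With Helios and FOXP3 the B cell markers averaged 0.61 and the myeloid markers 0.51 (camera adjusted p = 2.81e-05 and 3.62e-05; adjusted p = 0.557 and 0.0931 with an estimated correlation), with the myeloid lysozyme gene Lyz2 at 2.14, and 0.03 and 0.09 without Helios+FOXP3 replicate 2, and 0.09 and 0.44 without FOXP3 replicate 3, where both calls were lost. Limma with the set block called 0 genes for the 7 combinations, with 276 (Helios) to 1179 (EOS) at an unadjusted p under 0.05. Without the block 0 passed too, with 72 (Helios) to 542 (EOS). The smallest p-values were those of Gpatch3 with EOS (−0.82, adjusted p = 0.181), Aqp1 with GATA1 (−0.51), Cfap77 with Helios (−0.66), Ltb with IRF4 (−0.79), Tmem38b with LEF1 (1.38) and SATB1 (1.30), and Atp6v0e2 with XBP1 (−0.71), with adjusted p of 0.999 or 1 for the last 6.

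Whether a cofactor acted alike with and without FOXP3 was read from the interaction of the pair and from the correlation of its 2 effects. With the set block limma called 0 genes for the 7 interactions, with 227 (Helios) to 574 (GATA1) at an unadjusted p under 0.05. Without the block 0 passed too, with 44 (Helios) to 219 (GATA1). The smallest p-values were those of Tox4 (0.83) and Cfap77 (−1.13) for GATA1, Cfap77 also for IRF4 (−1.03), LEF1 (−0.83) and Helios, Aqp1 for SATB1 (−0.74), Ankrd34a for EOS (−0.78) and Cygb for XBP1 (−0.70), each with adjusted p = 1. Across genes, the effect of a cofactor without FOXP3 correlated with its effect in the presence of FOXP3 at a median r of 0.465 (range −0.0389 to 0.511 over 7 cofactors), and the effects of different cofactors at a median of 0.258 (range −0.159 to 0.556 over 42 pairs). With the set block these medians were 0.164 for the same cofactor (range −0.161 to 0.264) and 0.034 for different cofactors. Genes are not independent replicates, and these values describe the arrays only.

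The single FOXP3+Pbx1 array had no replicate, so its differences from the 2 FOXP3 arrays carry no test. Usp17ld, a deubiquitinase gene, was 6.27 higher on the log2 scale (12.02, against 5.03 to 6.13 in the other 32 arrays), followed by Tmem38b (2.60), the histone genes H2bc3 (2.38) and H4c6 (2.22), and Mzt1 (1.88). The difference of H4c6 was 1.27 without FOXP3 replicate 2 and 3.18 without replicate 3. Sec61b, which encodes a subunit of the protein translocation channel, was lower by −3.40, Eola1 by −3.34, Plac8 by −3.00, H2bc4 by −2.61 and Cox6a1 by −2.61. The level of H4c6 (10.88) lay inside the range of the other 32 arrays (7.707 to 10.9), and those of the other 9 genes outside it. Among 10000 random lists of like expression, the median of the cell cycle list (0.57) and that of the glycolysis list (0.48) lay at percentile 100, that of the naive list (0.30) at 99.9, and those of the Treg-up list (−0.37) and of the activation and NF-kB list (−0.53) at 0. These percentiles describe 1 array that formed a set of its own.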

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

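The tests of set C, of the vector arrays, of Thy1, of the set block and of splits inside the sets were chosen only after the results were seen, and the counts over other splits of the arrays were set beforehand.

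Cytotoxic genes, which encode granules and killer cell receptors, differed between backgrounds in how a cofactor moved them with and without FOXP3. Their interaction was 0.82 for GATA1 (10 of 10 genes positive, camera adjusted p = 0.00494; adjusted p = 0.477 with an estimated correlation). This call was lost without GATA1+FOXP3 replicate 2 (0.38), FOXP3 replicate 3 (0.58), vector replicate 2 (0.58) or GATA1 replicate 3 (0.83). The same list had an interaction of 0.65 for LEF1 (10 of 10, camera adjusted p = 0.000856; adjusted p = 0.365 with an estimated correlation), which was lost without LEF1+FOXP3 replicate 2 (0.29), FOXP3 replicate 3 (0.41) or LEF1 replicate 4 (0.48). GATA1+FOXP3 and LEF1+FOXP3 replicate 2 lay in set C, which held no array of FOXP3 alone, vector or a single cofactor and averaged 0.73 above the FOXP3 arrays of set B for this list. These 2 interactions were 0.65 and 0.48 with the set block (camera adjusted p = 0.00627 and 0.01; adjusted p = 0.41 for each with an estimated correlation). Immediate response genes of T cell activation and NF-kB had interactions of 0.71 for EOS and 0.61 for IRF4 (21 of 24 positive for each, camera adjusted p = 2.1e-05 and 5e-05; adjusted p = 0.396 and 0.443 with an estimated correlation). Both were lost without FOXP3 replicate 2 (0.39 and 0.28) or vector replicate 2 (0.45 and 0.34).

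With XBP1, a factor of the secretory pathway, the interaction was positive for 21 of 21 Treg-down genes (0.35), 16 of 16 naive T cell genes (0.44) and 18 of 20 cholesterol synthesis genes (0.33). Camera gave adjusted p = 0.0296, 0.0392 and 0.0015, and adjusted p = 0.782, 0.822 and 0.782 with an estimated correlation. The first 2 calls were lost without FOXP3 replicate 3 (0.14 and 0.09), XBP1 replicate 3 (0.15 and 0.17), XBP1+FOXP3 replicate 2 (0.29 and 0.28) or vector replicate 2 (0.34 and 0.34). The cholesterol call was lost without vector replicate 3 (0.05), XBP1+FOXP3 replicate 3 (0.09), FOXP3 replicate 2 (0.10) or XBP1 replicate 2 (0.24).

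The 5 fibroblast markers, of which Thy1 is also a T cell gene, had negative interactions for EOS (−0.20), SATB1 (−0.22), GATA1 (−0.23), IRF4 (−0.26) and XBP1 (−0.28). Camera gave adjusted p = 0.0287, 0.0043, 0.0185, 0.00438 and 0.000748, and adjusted p = 0.719, 0.571, 0.673, 0.571 and 0.49 with an estimated correlation. Without vector replicate 2 the values were −0.09, −0.10, −0.11, −0.14 and −0.16, and the first 4 calls were lost. They were also lost without FOXP3 replicate 3 (−0.15, −0.16, −0.17 and −0.21), without replicate 3 of EOS+FOXP3 (−0.13), GATA1+FOXP3 (−0.12) or IRF4+FOXP3 (−0.19), and without replicate 3 of EOS (−0.18), SATB1 (−0.07) or IRF4 (−0.24). All 7 interactions share the FOXP3 and vector arrays, so they are not independent.

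For the 172 genes called for FOXP3 in the 7 cofactor backgrounds, the Treg genes Lrrc32 and Il2ra among them, calls were recounted over other splits. Of 100 splits of the 4 arrays of each background, the real one included, 3 gave as many calls. The 2 other free splits gave 1263 and 1703, several times the real count, so this count alone cannot exclude chance. A structure of the samples may lie behind them, but splits with the same range of set B arrays on the FOXP3 side (4 to 11) gave 0 calls. When arrays changed sides only inside their set, which keeps set C with FOXP3, 1 of 100 gave as many calls (highest other 21). Each count was 1 of 100 with the set block (57 calls, against a highest of 2 and of 11). The counts inside the sets and with the set block argue against chance as the whole source of the calls. Set C as the whole source of the calls is argued against by FOXP3 against vector, which holds none of its arrays: 167 of the 172 genes had the same sign there, against 63.2% of all genes. For 4 lists the unequal share of the sets among arrays with and without FOXP3 may be the main source. Over 11 pairs inside sets A and B the mean was −0.0946 for Treg-down genes (SE 0.0585, −0.326 over all arrays) and −0.0941 for naive T cell genes (SE 0.0716, −0.465). It was 0.00275 for cell cycle genes (SE 0.0889, 0.278) and −0.0329 for ATF4 and CHOP genes (SE 0.0991, 0.437). These pairs include FOXP3 against vector, which the values over all arrays leave out. In set B that pair stood at −0.53, −0.68, 0.59 and 0.76 for the 4 lists. Treg-down genes stood at −0.19 in set A (lower in 3 of 3) and −0.0588 in set B. Without set C the 4 means were −0.116, −0.175, 0.28 and 0.258. Set C may thus be the main source for Treg-down and naive T cell genes. It stays open as a source for cell cycle genes and for ATF4 and CHOP genes. Leaving out set C left 5 combinations with only a set B array, against cofactors with arrays in sets A and B. Over FOXP3 arrays the cell cycle list averaged 8.118 in set A and 9.176 in set B. The value of 0.28 therefore cannot tell set C from that imbalance.

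Cell cycle genes such as Cenpe and Top2a were higher with 5 single cofactors than with vector, and a low vector array of replicate 3, the lowest of the 16 arrays of set B, is a candidate explanation for 4 of them. None of the 5 passed camera with an estimated correlation (adjusted p = 0.644 to 0.794), and the calls of the 4 were lost without 1 array (0.05 without LEF1 replicate 4, 0.03 without Helios replicate 3, 0.05 without SATB1 replicate 3 and −0.21 without EOS replicate 3). For EOS, Helios, LEF1 and SATB1 the mean difference from vector was 0.134 inside set A (SD 0.128, 3 of 4 above) and 0.649 inside set B (SD 0.0967, 4 of 4 above). For IRF4 the difference was 0.578 inside set A and 0.465 inside set B, which a low replicate 3 would not give, but 1 array per set cannot settle it. An effect of the other 4 cofactors on growth in set B alone stays open, since each set holds 1 vector array.

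Thy1, a surface protein gene of mouse T cells, was higher in 11 of 11 FOXP3 arrays of sets A and B than in every array of the same set without FOXP3 (4542 to 4813 against 1625 to 2399 in set A, and 3006 to 4092 against 2012 to 2717 in set B). A Thy1 sequence carried by the FOXP3 construct and a rise of the cell's own Thy1 transcript cannot be told apart, because both would part these arrays. The sample titles name the FOXP3 construct FIT, beside MIG for the vector and HIG for Helios, but do not spell out its parts.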

How the results depend on the processing

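The set block and leaving out set C were chosen after seeing the data, and the other settings beforehand.

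Treg-up genes kept their direction and their call by camera with a preset correlation in the 7 cofactor backgrounds in each setting run (adjusted p = 0.336 with an estimated correlation), and their shift over 8 backgrounds had exact p = 0.00781 in each, from 0.24 (set block) to 0.51 on leaving out 1 array. Treg-down genes did not: their mean in the 7 backgrounds (−0.326) was −0.0357 with the set block, with or without set C, and their shift over 8 backgrounds −0.069 (exact p = 0.188, lower in 5 of 8). For FOXP3 against vector their mean ranged from −0.534 (without FOXP3 replicate 2) to −0.115 (without FOXP3 replicate 3, where the call was lost) on leaving out 1 array.

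For FOXP3 in the 7 backgrounds, 172 calls became 101 with no filter, 57 with the set block, 8 without set C, 52 without set C with the set block, 1510 with the replicate number as a block, and 40 to 498 on leaving out 1 array (without EOS replicate 2 and LEF1+FOXP3 replicate 3). Leaving out set C left 5 combinations with only a set B array, against cofactors with arrays in sets A and B. The same arrays gave more calls with the set block, so fewer arrays alone do not account for the count without set C. Other causes were not tested. Quantile normalization, the mean over probes, an offset of 32 and only the comparison's arrays gave 156, 173, 171 and 163. The replicate number pairs only loosely (median r of 0.543 over 120 pairs of groups, from −0.153), and it joins sets A and C.

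For the other 22 comparisons limma called 0 genes with each setting except these: FOXP3 against vector had 6 with the set block and 1 without set C with the set block, IRF4 2 with the set block, LEF1 16 and its interaction 5 with the replicate block, and Helios+FOXP3 0 to 1 on leaving out 1 array (1 without Helios+FOXP3 replicate 3). Only LEF1 had a replicate 4, so the replicate block rested on its replicate 3 alone. That array lay in set A, while replicate 3 of the other groups lay in set B. The LEF1 counts with this block therefore cannot be read as effects of LEF1. Causes of the other counts were not tested.

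Of 575 list tests 184 passed camera, and 0 with an estimated correlation, 2 with fry for movement one way and 3 with fry for either direction, which do not compare a list with other genes. Leaving out 1 array gave 151 (FOXP3 replicate 2) to 202 (FOXP3 replicate 3). The cofactor effect with and without FOXP3, as a difference of median correlations (0.208), was 0.0592 with the replicate block, 0.13 with the set block, 0.0991 without set C with the set block, and 0.0283 (without FOXP3 replicate 3) to 0.326 (without Helios replicate 3) on leaving out 1 array.

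Signs reversed for some values. In the 7 backgrounds these were the ATF4-CHOP list (−0.106) and type I interferon list (0.100) with the set block, with or without set C, the interferon-gamma list without set C (−0.0261), and B cell markers with no filter (−0.0141) or the replicate block (−0.0449). The cell cycle list for LEF1 against vector was −0.195 with the replicate block. On leaving out 1 array, FOXP3 against vector ranged from −2.33 to 0.0678 for Ifi208 and −0.0396 to 0.765 for the glycolysis list, and the 7 backgrounds from −0.0786 to 0.0476 for Pim2 and −0.0713 to 0.117 for B cell markers. The cell cycle list ranged from −0.211 to 0.724 for EOS, and against FOXP3 from −0.0389 to 1.43 for GATA1, −0.519 to 0.945 for Helios and −0.0435 to 1.42 for LEF1. For the ATF4-CHOP list the unequal share of the sets may be the main source, as given above. The replicate block left LEF1 with 1 array that it did not match to vector inside a set. Leaving out set C or 1 array changed the balance of sets A and B. Over FOXP3 arrays these sets averaged 10.19 and 9.73 for interferon-gamma genes, and 8.118 and 9.176 for cell cycle genes. Other causes were not tested. A lone array left in a group is assumed to vary like the other groups. The intensities of Foxp3 and Gata1 lay near those of arrays without the factor, and whether background or probe coverage limits them was not tested.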

Other observations

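The tests inside sets A and B were chosen only after the results were seen. So were Gbp3, Gbp7, Iigp1, Gbp4, Tap1, Fosb, Nfkbia, Jun, Nr4a1, Nr4a3, Tnfaip3, Rel and Satb1 as genes to name here.

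Interferon-gamma response genes, which include the GTPases that defend cells against intracellular microbes, were higher with FOXP3 inside set B in 8 of 8 backgrounds. Their list averaged 0.19 (SD 0.0242, n = 8, 2-sided exact sign-flip p = 0.00781, 0.0325 after adjustment over 25 lists). Gbp7, a guanylate-binding protein gene, averaged 0.41 (SD 0.231, higher in 8 of 8), Iigp1, an immunity-related GTPase gene, 0.71 (SD 0.331, 8 of 8), and Gbp3 0.43 (SD 0.239, 7 of 8). In the 3 backgrounds of set A the list averaged 0.09 (SD 0.016, 3 of 3). Gbp7, Iigp1 and Gbp3 averaged 0.44, 0.22 and 0.58 there, while Gbp4 (−0.004) and Tap1 (0.004) stayed near 0. Over the 7 cofactor backgrounds the list did not pass camera over all arrays (0.13, adjusted p = 0.259). It passed with the set block (0.15, camera adjusted p = 0.00333, and adjusted p = 0.41 with an estimated correlation). Its mean was −0.03 without set C, where 5 combinations kept only a set B array. Over FOXP3 arrays the list averaged 10.19 in set A and 9.73 in set B. The mean without set C therefore does not tell whether the shift depends on set C.

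Immediate response genes of T cell activation and NF-kB were also higher with FOXP3 inside set B in 8 of 8 backgrounds, with a mean of 0.30 (SD 0.114, n = 8, exact p = 0.00781, 0.0325 after adjustment). Over the 7 cofactor backgrounds the list did not pass camera over all arrays (0.11, adjusted p = 0.0604) and passed with the set block (0.18, adjusted p = 0.000336; adjusted p = 0.585 with an estimated correlation). The AP-1 gene Fosb averaged 1.62 (SD 1, 8 of 8), Nfkbia, which encodes an inhibitor of NF-kB, 0.46 (SD 0.278, 8 of 8) and Jun 0.60 (SD 0.568, 6 of 8). Other members moved little there, with Nr4a1 at 0.13, Nr4a3 at 0.13, Tnfaip3 at 0.10 and Rel at −0.11. In set A the list averaged −0.49 (SD 0.309, 0 of 3 higher), Fosb −0.90 (0 of 3 higher), Nfkbia −0.12 (1 of 3) and Jun 0.42 (2 of 3). Nr4a1 (−2.81), Nr4a3 (−2.33) and Tnfaip3 (−1.37) were lower still in set A, each higher in 0 of 3. The difference between the sets was not tested.

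Set C differed from the other FOXP3 arrays in groups of effector genes. Over the arrays with FOXP3, Th2 genes averaged 7.99 on the log2 scale in set C against 7.11 in set B and 6.95 in set A, effector genes of IRF4 and BLIMP1 8.67 against 7.75 and 7.66, and Treg-up genes 9.04 against 8.57 and 8.44. Satb1, a chromatin organizer of T cells, had intensities of 5226 to 7845 in set A, 3001 to 4679 in set B and 2845 to 3570 in set C.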
